A study of Mus musculus with 6 samples.

How the data were processed

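DNA methylation was measured by reduced representation bisulfite sequencing (RRBS) of Achilles tendons from male C57BL/6 mice. Per the labels' protocols, each library was made from 200 to 500 ng of DNA of 5 to 6 tendons. The DNA was digested with TaqαI and MspI, and fragments of 150 to 250 bp and of 250 to 350 bp with adaptors were recovered from a gel. They were then treated with bisulfite, amplified by PCR and sequenced on an Illumina HiSeq. The submitters' processing notes name Bismark, a bisulfite aligner and methylation caller. Its version, the genome build and any removal of duplicate reads are not given in the sources used here.

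The authors deposited 5 tables, each setting the uninjured library beside 1 injured library. A table lists a CpG on each strand separately, and only where both libraries have 5 or more reads. The methylation level is a fraction that the authors computed as methylated reads over all reads and rounded to 2 decimals. The read total at each CpG is a count, per the file headers, with no normalization. The deposited difference is the uninjured level minus the injured level, so the authors' hypomethylated classes hold CpGs with a higher level in the injured library. The deposited p-value was checked at CpGs with a difference over 0.1 and at most 100 reads in each library, where it equalled an unadjusted two-sided Fisher's exact test on the reads (within 0.01 log10 units) at 99.9981% or more of them in each table. CpGs with more reads were not checked. It is set to 1 where the levels differ by less than 0.1, and the authors' changed classes hold CpGs with a p of at most 0.05 and a difference of at least 0.1. Uninjured values are identical in the 5 tables. No per-sample value column was left unused.

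Methylated reads were recovered here as level times total, rounded, which is exact up to 100 reads. The share of listed CpGs above 100 reads was between 0.0892% and 3.29% per library and table. The gene table used here (RefSeq, assembly GRCm38.p6) fits the deposited coordinates. Of 495396 CpGs within 500 bp of an end of a gene, 93.5% were less than 10% methylated, against 56.0%, 57.2% and 49.7% after shifts of 5000, 100000 and 1000000 bp. Positions are printed as the deposited tables give them, and whether they count from 0 or from 1 is not given in the sources used here. The gene table has no strand, so the start and the end of a gene could not be told apart. The planned unit was the promoter, and the planned fallback for this case, tiles of 1000 bp, replaced it. A tile within 1000 bp of either end of a gene is called a gene-end tile below and carries the name of that gene, or of each such gene where there are several.

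Groups were taken from the labels. There was 1 library per group, 6 groups and 9 comparisons, namely each injured library with the uninjured library, treadmill with cage at each day, and day 28 with day 14 in each activity group. For each CpG with at least 10 reads in both libraries, a two-sided Fisher's exact test was run on the reads, with Benjamini-Hochberg adjustment over the CpGs of the comparison. A CpG was called where the adjusted p was under 0.05 and the levels differed by at least 20 percentage points (points below). For each tile with at least 3 such CpGs, the mean difference over CpGs was taken with its standard deviation (SD) over CpGs, and Fisher's exact test was run on the summed reads with the same adjustment over tiles. A tile was called where the adjusted p was under 0.05, the mean difference was at least 10 points and at least 66.7% of its CpGs moved that way. A read that spans several CpGs enters the tile's sum once per CpG, so the tile p-values are too small. An adjusted p printed for a tile below is from this test. The SD over CpGs describes the CpGs of a tile and not samples.

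Depth was 46904965 to 61430853 reads summed over listed CpGs per library, with a median of 15 to 18 reads per CpG. A read spanning several CpGs counts at each in these sums. PCR reads without molecular identifiers are not independent molecules, so p-values and intervals cover counting error only. In data simulated for the day 3 comparison (125011 tiles, 1570735 CpGs, 200 tiles changed by 10, 20 or 30 points), 1.49%, 22.4% and 56.1% of the changed tiles and 0%, 0% and 0.274% of the changed CpGs were called. Among the unchanged, 2 tiles and 0 CpGs were called. With only 200 tiles changed, the adjustment was stricter there than in the day 3 data, where 8947 tiles were called. A change of 10 points also equals the calling threshold for tiles. The shares therefore hold for that setting and do not measure what depth alone allows.

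Named genes were chosen by a fixed rule. For each comparison with the uninjured library they are the 6 called gene-end tiles with the largest mean rise and the 6 with the largest mean fall, up to 4 called members of each gene list by size, and the 5 genes of the study's title whatever their values. For treadmill against cage they are the 5 largest called rises and the 5 largest called falls, and those called in 1 direction on both days. For day 28 against day 14 they are up to 5 each way called in both activity groups. Predicted genes without a symbol of their own were counted and passed over in naming. Some tiles that the rule picked are not reported here. The 15 gene lists were the study's title genes, tendon lineage and matrix, cartilage and bone, TGF-beta and BMP signalling, extracellular proteases and inhibitors, collagen-modifying enzymes, the IGF axis, imprinted genes, limb and body-plan transcription factors, inflammation, and markers of immune cells, skeletal muscle, fat, endothelium and keratinocytes. A gene counts as measured where it is protein-coding and has a tested gene-end tile. The median difference of a list was placed among those of 10000 random lists of the same size, matched on methylation level in 10 bins, as a description of these libraries. A tile near several genes counts for each of them. The random lists were not matched on genes lying side by side, such as the Hox genes. Lists, the tests of the comparisons, thresholds, the naming rule and most alternatives were fixed before the data were examined. The tests per strand and several tests of explanations were chosen after results were seen.

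As further comparisons, CpGs with at least 10 reads in all 6 libraries were counted where 1 library lay 20 points or more above or below all the other libraries. Tiles with at least 3 such CpGs were counted at a gap of 10 points or more. Calls shared between comparisons without a common library were tested with an exact binomial test of an even split. Overlaps of comparisons that share the uninjured library were set beside 20 simulations of unchanged libraries, with reads drawn at the level of the uninjured library, and beside the number that independent lists would share. Because strands are sequenced as separate molecules after bisulfite treatment, tiles were also tested on the plus and the minus strand apart. These tests took only CpGs with at least 10 reads on both strands in both libraries, and tiles with at least 3 of them. The strands of 1 library were also tested against each other as a measure of spread within a library. Alternatives changed the minimum of reads or CpGs, the thresholds and the depth, left out the most deeply covered CpGs (a coverage cap) or the sex chromosomes, or changed the averaging or the test. Strands summed, calls on both strands and leaving out the day 3 library were added after seeing the data. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9.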

Results

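CpG methylation was profiled by RRBS in Achilles tendons of uninjured mice and of mice with tendinopathy induced by 2 injections of transforming growth factor beta 1 (TGF-β1) into the tendon. Injured tendons were collected on day 3 (the acute response), or on day 14 or 28 (the chronic response) after either cage activity or treadmill running. Each of the 6 groups was represented by 1 library, made from the DNA of 5 to 6 tendons. There were no replicates, so every test on reads compared 2 libraries and not 2 conditions. Reads summed over listed CpGs, where a read spanning several CpGs counts at each, were 54789505 in the uninjured library and 49251980 at day 3. The day 14 libraries had 61430853 (cage) and 55762645 (treadmill), and the day 28 libraries 46904965 (cage) and 47156419 (treadmill). The uninjured sum covers 2529833 CpGs and the injured sums 2179790 to 2336207 CpGs each. At the 1125769 CpGs with at least 10 reads in all libraries, sums were 38261727 (uninjured) and 35426987 (day 3). There they were 46689944 and 40499566 at day 14 and 29600650 and 28909627 at day 28 (cage, treadmill). The library names carry 1 prefix for the day 28 libraries and another for the remaining libraries, and whether the prefixes mark separate batches is not given in the sources used here. If they do, day 28 and library batch cannot be told apart.

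Mean methylation over the 1125769 CpGs with at least 10 reads in all 6 libraries was 28.8% in the day 3 library, 27.5% in the uninjured library and 27.6% to 28.1% in the others. CpGs within 1 kb of a gene end averaged 9.01% at day 3 and 8.55% in the uninjured library. CpGs inside genes averaged 49.8% and 47.7%, and CpGs between genes 62.0% and 59.1%. In each of these 3 classes the day 3 library had the highest mean of the 6, with the day 28 cage library close to it at gene ends (9.0%). With at least 20 reads per CpG the means were lower, 15.0% in the day 3 library and 14.1% in the uninjured library. Between libraries, levels correlated across CpGs with Pearson's r from 0.959 (day 28 cage with day 3) to 0.972 (day 14 treadmill with day 14 cage), where CpGs are not independent replicates.

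The comparison of the day 3 library with the uninjured library addressed the acute response. In the day 3 library 5 of 40 TGF-beta and BMP signalling genes and 4 of 22 collagen-modifying enzymes were called higher at gene ends and 0 lower. Of 72 limb and body-plan transcription factors, among them the Hox genes, 13 were called lower and 5 higher. Most genes of each list were not called. Mcts2, an imprinted retrogene, rose from 7.81% to 59.4%, a mean difference of 51.6 points (SD 5.84 over 12 CpGs; chromosome 2, 152686000 to 152686999; adjusted exact p = 3.38e-22). Serping1, which encodes the C1 inhibitor of complement, rose from 3.23% to 50%. Yeats4, a reader of acetylated histones, fell from 70.4% to 21.9%, a difference of -48.5 points (SD 12.6 over 15 CpGs; chromosome 10, 117215000 to 117215999; adjusted exact p = 5.10e-42). The other largest rises were at Zfp521 (45.8 points), Tbc1d9 (44.9), Fads6 (43.3) and the ATP synthase subunit gene Atp5e (42.3). The other largest falls were at the ciliary gene Cfap45 (-51.0 points), Scarletltr (-48.1), Ripor2 (-46.2), the ERK phosphatase gene Dusp5 (-45.5) and Fam110a (-43.4).

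Of 125011 tested tiles, 6609 were called higher and 2338 lower in the day 3 library, and of 34358 gene-end tiles 1129 were higher and 470 lower. These tiles covered 690 protein-coding genes with higher and 279 with lower methylation among 14992 measured. At single CpGs 904 were higher and 542 lower of 1570735 tested. The strands were tested apart in the 37997 tiles measured on both. There 2045 tiles were called on the plus strand and 1948 on the minus strand. In 85.2% of them the other strand differed in the same direction. Tests between the strands of 1 library called 628 tiles in the day 3 library and 602 in the uninjured library, a measure of spread within a library. On both strands alone and in 1 direction, 715 tiles were called. Of the 60 named tiles, 18 could be measured on both strands, and 17 of these differed in the same direction on both and 6 were called on both.

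**Figure D1:**
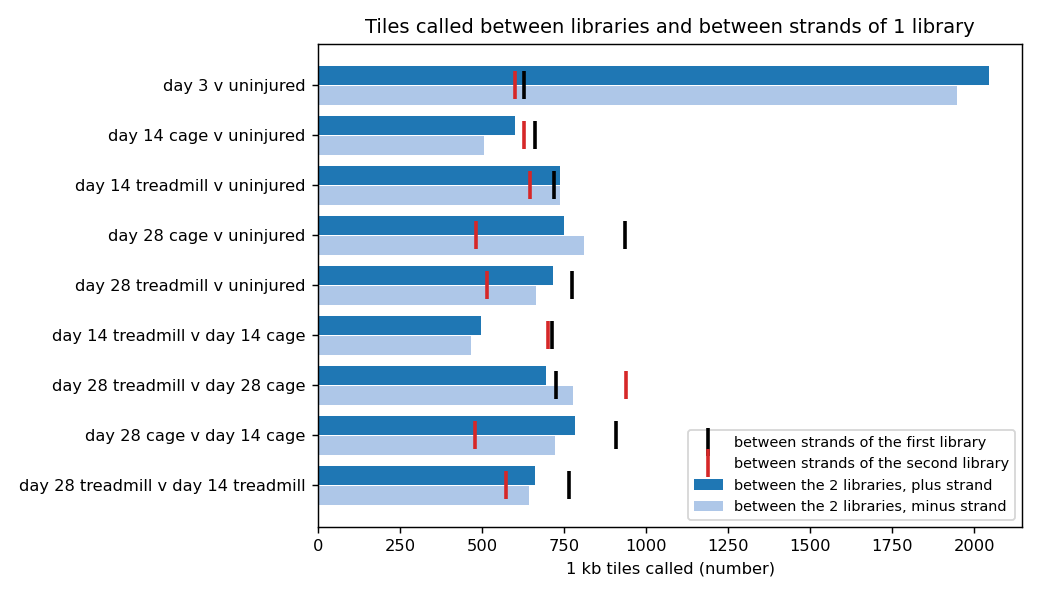
Bars give the number of 1 kb tiles called between 2 libraries on the plus strand and on the minus strand, for each of the 9 comparisons, and ticks give the number called between the strands of the first (black) and the second (red) library. Day 3 against uninjured stands at 2045 and 1948 tiles with ticks at 628 and 602, while in the other comparisons both bars and ticks lie between 466 and 939.

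Among tendon lineage and matrix genes, 5 were higher and 1 lower of 24 measured at day 3, and the counts were the same adjusted over the list alone, where random lists gave means of 1.52 and 0.594. Col1a2, a chain of type I collagen, rose from 3.85% to 27.1%, Fbn1 (fibrillin-1) rose by 31.9 points and Thbs2 (thrombospondin 2) by 20.2 points. The list's median difference of 1.34 points stood at percentile 99.8 of the random lists. Collagen-modifying enzymes had 4 higher and 0 lower of 22 measured, and 6 and 0 adjusted over the list alone, where random lists gave means of 1.46 and 0.621, with the median at percentile 94.3. They included the prolyl 3-hydroxylase gene P3h1 (25.5 points over 8 CpGs) and the collagen chaperone gene Serpinh1 (23.3 points). The tile shared by Loxl4 and R3hcc1l (17.4 points) turned to -0.500 points with a minimum of 5 reads. Of 40 TGF-beta and BMP signalling genes, 5 were higher and 0 lower, the same adjusted over the list alone, where random lists gave means of 1.37 higher and 0.511 lower, and the median stood at percentile 86.7. The ligand gene Tgfb3 rose from 11.7% to 45.0%. Ski, a SMAD co-repressor, rose from 8.71% to 31.4% (adjusted exact p = 7.51e-11), and Smad5 from 9.44% to 25.9% (adjusted exact p = 9.31e-10), both also called on each strand alone. The activin receptor gene Acvr1b rose by 20.4 points.

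The IGF axis had 3 higher and 0 lower genes of 16 at day 3, the same adjusted over the list alone (random lists 0.734 and 0.260), with the median at percentile 20.8. The receptor gene Igf1r rose from 2.59% to 26.8% and its substrate gene Irs2 by 25.3 points. Among extracellular proteases and inhibitors, Mmp14 alone of 27 genes was called, higher by 23.0 points, also adjusted over the list alone (random lists 0.831 higher, percentile 82.4). In the cartilage and bone list 1 gene was higher and 1 lower of 28, the same adjusted over the list alone (random lists 1.67 and 0.670, percentile 55.2). Sp7 (osterix), a transcription factor of osteoblasts, fell from 71.1% to 33.3% (SD of the difference 8.68 points over 9 CpGs, adjusted exact p = 7.91e-12, called on each strand alone), and the tile shared by the cartilage matrix gene Comp and by Crtc1 rose by 12.5 points. Imprinted genes had 4 higher and 2 lower of 32, and 5 and 3 adjusted over the list alone, where random lists gave means of 3.17 and 1.36, with the median at percentile 8.40. H19, a non-coding RNA gene outside these counts, rose from 21.2% to 53.6%, Snurf rose by 28.0 points, and the growth inhibitor gene Cdkn1c fell by 26.9 points.

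Limb and body-plan transcription factors had 5 higher and 13 lower genes of 72 at day 3, and 6 and 15 adjusted over the list alone, where random lists gave means of 4.87 higher and 1.98 lower genes. The list's median of -0.246 points stood at percentile 0.03. Hox genes lie in clusters and can share a tile, so these counts and the percentile may overstate the difference from random lists. Hoxc6 fell from 44.7% to 16% (SD of the difference 11.8 points over 10 CpGs; chromosome 15, 103012000 to 103012999; adjusted exact p = 3.20e-18), Tbx18 fell by 32.8 points, the hindlimb gene Pitx1 by 27.9 points and Hoxc9 by 22.9 points. In the inflammation list 3 genes were higher and 2 lower of 29, and 3 and 4 adjusted over the list alone (random lists 1.87 and 0.769, percentile 9.37). The cytokine genes Tnf and Il10 each fell by 23.6 points and Socs3 rose by 14.4 points. Il6ra rose by 19.9 points, with opposite signs on the strands (30.2 and -13.4 points).

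Some markers of other cell types were called at day 3, and most were not. Among immune markers 2 were higher and 2 lower of 17, the same adjusted over the list alone, where random lists gave means of 1.66 and 0.733, and the median of -0.734 points stood at percentile 1.21. The leukocyte integrin genes Itgam and Itgal fell by 35.2 and 27.8 points, while the tile of Cd37 and Slc6a16 rose by 24.1 points and Fcer1g by 12.7 points. Skeletal muscle markers had 4 higher and 1 lower of 25, and 5 and 1 adjusted over the list alone (random lists 2.08 and 0.858, percentile 60.6), with Pygm 26.5, Casq1 25.8 and Mylpf 14.3 points higher and the myogenic factor gene Myog, in a tile with Myoparr, lower by a difference of -25.3 points. Fat markers had 4 higher and 1 lower of 16, the same adjusted over the list alone (random lists 1.01 and 0.421, percentile 95.3), with Pck1 (29.2 points), the leptin gene Lep (26.4), Cfd (25.8) and Fabp4 (19) higher. Endothelial markers had 3 higher and 1 lower of 21, and 3, 1 and 1 with tiles in both directions adjusted over the list alone (random lists 1.66 and 0.676, percentile 33.6). Pecam1 was 27.4 points higher, the tile of Rasip1 and Mamstr 25.2 and Nos3 19.7, and Plvap fell by 29.1 points. Keratinocyte markers had 3 higher and 0 lower of 18, the same adjusted over the list alone (random lists 1.45 and 0.591, percentile 95.3), with Epcam 41.0 points, Krt10 23.7 points and Cldn4 12.1 points higher.

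**Figure D2:**
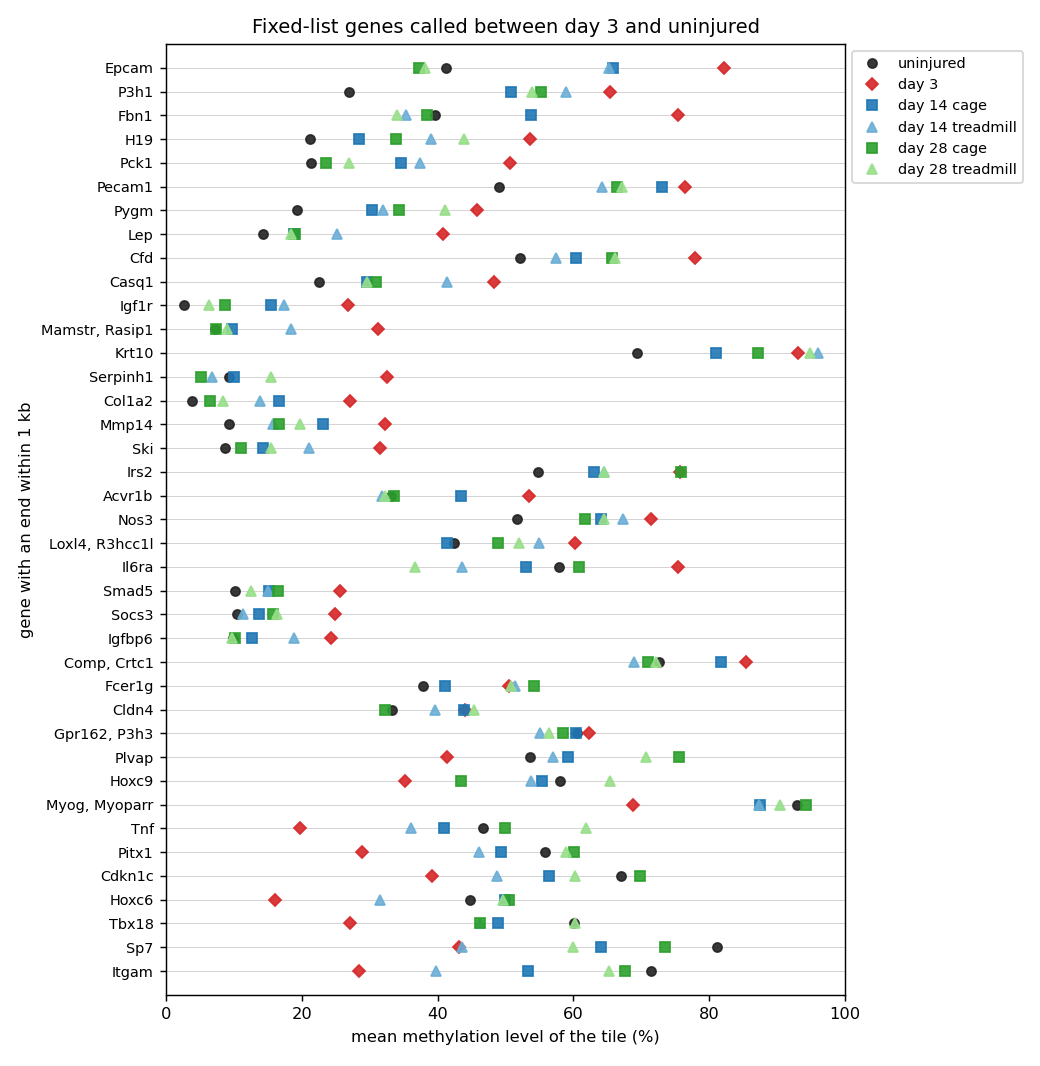
Each point is the mean methylation level (percent) of 1 library over the CpGs of a named gene-end tile with at least 10 reads in all 6 libraries, for genes of the fixed lists called at day 3, sorted from the largest rise to the largest fall. Hoxc6 (16% at day 3, 44.7% in the uninjured library) and Igf1r (26.8% and 2.59%) are examples of either direction.

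At day 14 with cage activity, the chronic response at this time, far fewer tiles differed from the uninjured library. The imprinted genes Nap1l5 (from 22.8% to 42.4%, SD of the difference 12.3 points over 22 CpGs, adjusted exact p = 2.17e-06) and Mcts2 (from 20.2% to 40.9%, adjusted exact p = 6.22e-06) were higher. The endothelial genes Pecam1 (24.1 points) and the tile of Esam and Msantd2 (10.3 points) were also higher. The largest rises were at Rundc3a (41.0 points), Tmem189 (32.4), the tile of Arl6ip4 and Pitpnm2 (31.0), the tile of Plekho1 and Vps45 (28.7), Cep295nl (28.3) and the limb gene Hoxd9 (27.3, tile at 74701000 of chromosome 2). The largest falls were at Anapc4 (-39.8 points), a subunit gene of the anaphase-promoting complex, Tmem95 (-32.4), the erythroferrone gene Erfe (-30.1), H2-M6-ps (-29.0), Tmem138 (-28.4) and Clba1 (-28.3). Gdf5, a growth factor gene of joint and tendon formation, rose by 10.5 points and the imprinted non-coding gene Meg3 by 12.6 points, but with a minimum of 5 reads these were -1.03 and -3.99 points.

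In that comparison 844 tiles were higher and 646 lower of 119997, with 156 and 102 at gene ends, and 75 CpGs were higher and 75 lower of 1531724. By gene, 103 were higher and 52 lower. Of the named tiles 6 could be measured on both strands, with the same sign in all 6, and 0 were called on both. On single strands 600 and 507 tiles were called, and tests between the strands of the day 14 cage library called 663 and of the uninjured library 628. The sign was shared by the other strand in 63.0%. Of 32 imprinted genes 2 were higher and 1 lower, and 3 and 1 adjusted over the list alone. Endothelial markers had 2 higher and 0 lower of 20, and tendon lineage and matrix genes 1 higher and 0 lower of 25, both the same adjusted over the list alone. Limb and body-plan transcription factors had 1 higher and 0 lower of 72, and 2, 1 and 1 with tiles in both directions adjusted over the list alone. No gene of the other lists was called, but adjusted over the list alone 2 inflammation genes and 1 IGF axis gene were higher. Fat markers had their median at percentile 98.6.

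At day 14 with treadmill running, the bone gene Sp7 fell from 81.1% to 43.6% over 3 CpGs, and Itgam, an integrin gene of myeloid cells, fell from 71.4% to 39.7%. The imprinted genes Nap1l5 (from 22.8% to 50.5%, SD of the difference 9.41 points over 22 CpGs, adjusted exact p = 3.52e-16), Peg13 (22.2 points), Mcts2 (22.1 points, in the tile from 152687000) and H19 (18.8 points) rose, and Nap1l5, Peg13 and H19 were called on each strand alone. Ski rose by 12.3 points and Igf1r by 14.8 points. Tbx4, which patterns the hindlimb, rose from 12.5% to 47.9% and En1 by 16.9 points, while Tbx18 fell by 20.5 points and Hoxc6 by 13.3 points. Other large rises were at Tmem189 (39.4 points), Cep295nl (38.4), Dhx35 (33.9) and Stac (32.3). Other large falls were at Crybg2 (-50.0 points), Tmem138 (-37.9), Anapc4 (-36.0) and the vimentin gene Vim (-34.9).

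This comparison had 1240 tiles higher and 1024 lower of 128863, with 222 and 162 at gene ends, 126 and 92 genes, and 114 and 104 CpGs. With a threshold of 20 points 470 and 466 tiles were called, with sign flips over CpGs 77 and 13, and with the strands of a CpG summed 126 and 163 CpGs. Strands tested apart gave 739 tiles each, beside 720 and 647 called between the strands of the 2 libraries, and 67.2% shared the sign. Limb and body-plan transcription factors had 3 higher and 2 lower of 72, and 3 and 4 adjusted over the list alone. Imprinted genes had 2 higher and 2 lower of 31, the same adjusted over the list alone. Immune markers had 0 higher and 2 lower of 17, and 1 and 2 adjusted over the list alone, the second fall being at Ikzf1 (-15.3 points). In each of 6 further lists 1 member was called, with the same counts adjusted over the list alone. They were Sp7, Ski and Igf1r and, among cell-type markers, Casq1 (18.8 points), the nitric oxide synthase gene Nos3 (14.4 points) and Krt10 (26.6 points). The medians of the tendon lineage and matrix list (percentile 99.8, 0 of 25 called) and of the title genes (98.1) were high among random lists.

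At day 28 with cage activity, Hotair, a non-coding RNA gene in the HoxC cluster, rose from 22.7% to 68.8% (46.0 points, SD 3.93 over 4 CpGs). The HoxC genes Hoxc4 (16.4 points) and Hoxc10 (16 points) were higher too, while Hoxd9 (-16.1 points) and Tbx18 (-17.8 points) were lower. This Hoxd9 tile (chromosome 2, 74699000 to 74699999) is not the one called at day 14, and it had 11.4% in the day 14 cage library and 23.2% in the uninjured library. Mcts2 rose from 20.2% to 50.2% over 24 CpGs of the tile from 152686000 (adjusted exact p = 1.77e-14) and Nap1l5 from 22.8% to 39.3%, both called on each strand alone. The next tile of Mcts2 was not called, with 21.7% in the uninjured and 27.5% in the day 28 cage library over 7 CpGs. Peg13 rose by 15.7 points, and the tile of Peg3 and Usp29 fell from 38.6% to 22.9%. Sox5, a transcription factor of chondrocytes, rose by 26.9 points and Msx1 by 13.8 points. Other large rises were at Ube2uos (39.5 points), Nuggc (36.5), the leukocyte gene Arhgap9 (35.1), the tile of Ankrd2 and Hoga1 (34.2) and Taf7l (32.0). Large falls were at Crybg2 (-46.6 points), Erfe (-41.6), Nr2f1 (-38.5), Rrp36 (-36.5), the tile of Arf5 and Fscn3 (-35.9) and Pmepa1 (-30.1), a TGF-beta target gene.

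Tiles called were 1133 higher and 692 lower of 118133, with 246 and 111 at gene ends, 143 and 77 genes, and 160 and 104 CpGs. Strands tested apart gave 750 and 811 tiles, beside 935 between the strands of the day 28 cage library and 481 between those of the uninjured library, and 57.4% shared the sign. Limb and body-plan transcription factors had 4 higher and 2 lower of 72, and 6 and 3 adjusted over the list alone. Imprinted genes had 2 higher and 2 lower of 34, and 3 and 2 adjusted over the list alone. Cartilage and bone genes had 2 higher and 0 lower of 28, the same adjusted over the list alone. Immune markers had 1 higher and 0 lower of 14, and 2 and 1 adjusted over the list alone. Pck1 (17.4 points, in a tile that was also higher at day 3, by 15.5 points) was the 1 fat marker called, also adjusted over the list alone, where 2 collagen-modifying enzymes were higher as well.

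At day 28 with treadmill running, Hotair rose from 22.7% to 53.0%, and Pitx1 (17.3 points), Hoxc6 (13.7 points), Hoxc5 (12.9 points) and the tile of Hoxb3, Hoxb5 and Hoxb5os (17.5 points) rose as well. The Pitx1 tile (chromosome 13, 55835000 to 55835999) is not the one called lower at day 3, where the day 28 treadmill library had 58.9% and the uninjured library 55.8%. The Hoxc6 tile (chromosome 15, 103011000 to 103011999) was lower at day 3, by a difference of -17.6 points, beside the tile named there. The lysyl hydroxylase gene Plod3 rose from 70.9% to 96.7% over 3 CpGs. Among imprinted genes H19 rose from 21.2% to 43.9% (SD of the difference 12.4 points over 7 CpGs, adjusted exact p = 2.54e-05, called on each strand alone), Nap1l5 by 16.7 points and the tile of Peg3 and Usp29 by 13.8 points. The next tile of H19 rose by 13 points, but with a minimum of 5 reads its difference was -8.61 points. Of the named tiles 11 could be measured on both strands, of which 2, this tile of H19 and Cldn4, had opposite signs and 1 was called on both. Among the largest rises were Stk33 (38.1 points), Rundc3a (34.1), Bhmt-ps1 (30.5) and the tile of Adcy4 and Ripk3 (28.9). The largest falls were at Avpi1 (-35.0 points), Eif3a (-34.9), Wnk2 (-33.1), Ighv1-10 (-30.8), Prss22 (-29.4) and Polm (-27.7).

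Here 1118 tiles were higher and 597 lower of 117050, with 221 and 88 at gene ends, 149 and 44 genes, and 128 and 63 CpGs, or 130 and 112 with the strands of a CpG summed. Strands tested apart gave 716 and 664 tiles, beside 775 and 514 between the strands of the 2 libraries, and 59.6% shared the sign. Limb and body-plan transcription factors had 5 higher and 0 lower of 72, and imprinted genes 3 and 0 of 33, both the same adjusted over the list alone. Collagen-modifying enzymes had 1 higher and 0 lower of 21, and 3 and 0 adjusted over the list alone. Keratinocyte markers had 1 higher (Cldn4, 11.9 points) of 18, and 2 adjusted over the list alone. The same count either way held for 1 fall in the inflammation list (Il6ra, -18.0 points) and 1 rise each among immune markers (the tile of Cd37 and Slc6a16, 22.9 points), muscle markers (Pygm, 21.9 points) and endothelial markers (Nos3, 12.3 points). The median of the endothelial markers stood at percentile 99.

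**Figure D3:**
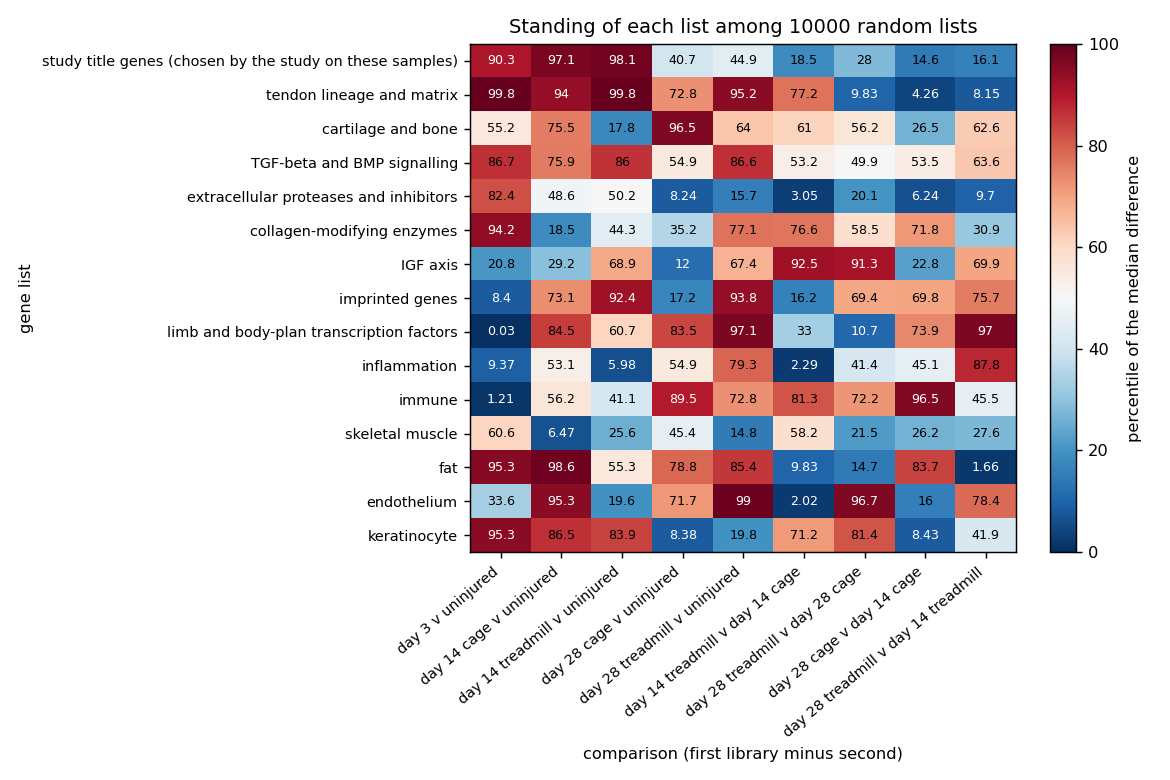
For each of the 15 gene lists and 9 comparisons, the percentile of the list's median gene-end difference among 10000 random lists matched on methylation level is shown. The median lay outside the central 95% in 10 of 135 pairs, where 6.75 would lie at 5%, and in 3 of these the comparison was day 3 against uninjured.

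Some genes differed from the uninjured library in several injured libraries. At Nap1l5 the uninjured library had 22.8% and the injured libraries 39.3% to 50.5% over the 22 CpGs measured in all 6, and at 1 tile of H19 21.2% against 28.4% to 53.6%. At the next tile of H19 the uninjured level of 30.8% lay within the injured levels of 25.7% to 43.8%. At 2 tiles picked for this comparison after their values were seen, the gap was larger still or went the other way. At P3h1 the uninjured level was 26.9% against 50.8% to 65.4% over the 4 CpGs measured in all 6, where over 8 CpGs day 3 and uninjured had 68.1% and 42.6%. Angptl4, which encodes an inhibitor of lipoprotein lipase, had 37.0% against 6.75% to 18.6%. Of 89700 tiles tested in all 5 comparisons with the uninjured library, 2026 were called in 1 direction in 2 or more (1436 higher and 590 lower), and 990 when the day 3 library was left out. Unchanged libraries simulated against the uninjured library gave 0.3, but the simulations hold counting error only and leave out the spread between separate libraries, which was not measured. All 5 comparisons called 48 tiles, 30 higher and 18 lower. Between the 2 day 14 libraries 217 higher and 167 lower tiles were shared, where independent lists would share 7.34 and 4.08. The covariance of their differences was 20.8 squared points, beside 9.38 in the simulation. For day 3 and day 14 treadmill the shared higher tiles were 621, where independent lists would share 59.0 (covariance 25.6, simulated 9.32). For the 2 day 28 libraries they were 176 and 9.86 (covariance 18.2, simulated 9.38). Part of each excess may come from the shared uninjured library, which cannot be split.

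Each library was compared with all others at once. Over the CpGs measured in all 6 libraries, the uninjured library lay 20 points or more beyond all others at 4040 CpGs (1100 above and 2940 below). The day 3 library did so at 12174 CpGs (7837 above and 4337 below), the day 28 cage library at 7175, the day 28 treadmill library at 5801, the day 14 cage library at 3707 and the day 14 treadmill library at 3239. With all libraries thinned to 10 reads at each CpG the numbers were 35180 for the day 3, 24990 for the uninjured, 30173 and 26395 for the day 28 and 24371 and 24882 for the day 14 libraries (cage, treadmill). The uninjured library had rank 4 of 6 in both, and rank 3 of 5 when the day 3 library was left out. For tiles the gap was set at 10 points or more, over 85085 tiles. The numbers were 922 for the uninjured and 4363 for the day 3 library. They were 1045 and 939 for the day 28 and 655 and 660 for the day 14 libraries (cage, treadmill).

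**Figure D4:**
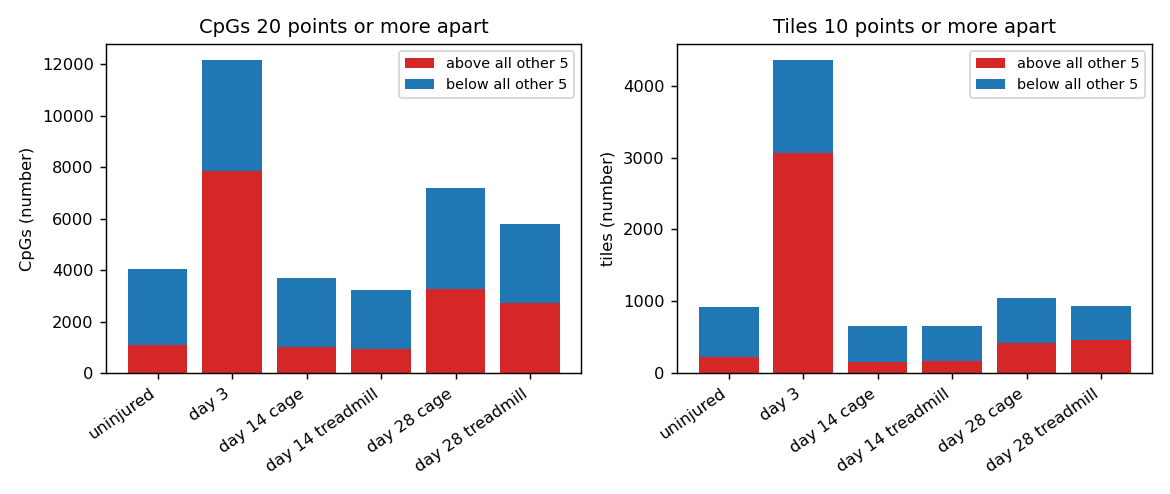
For each of the 6 libraries, bars give the number of CpGs at which its methylation level lay 20 percentage points or more above, or below, the levels of all other libraries. The day 3 library has 12174 such CpGs and the uninjured library 4040.

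The series title names P3h3 (formerly Leprel2), a prolyl 3-hydroxylase of collagen, the transcription factor gene Foxf1, the matrix metalloproteinase gene Mmp25, the IGF-binding protein gene Igfbp6 and the imprinted gene Peg12. The study chose them on these samples, so their values are not independent evidence. Igfbp6 (chromosome 15, 15 CpGs measured in all 6 libraries) averaged 9.89% in the uninjured library, 24.3% at day 3, 12.7% and 18.9% at day 14 with cage and treadmill, and 10.2% and 9.71% at day 28. Its gene-end tile rose from 10.5% to 22.0% at day 3 (SD of the difference 14.5 points over 25 CpGs, adjusted exact p = 1.73e-06). On CpGs measured on both strands it differed by 6.41 and 7.67 points, and it was not called on both. Peg12 (chromosome 7, 44 CpGs) averaged 12.9% in the uninjured library, then 17.1%, 16.8%, 16.7%, 12% and 18.3% in the same order. Mmp25 (chromosome 17, 66 CpGs) averaged 13.4%, then 14.8%, 15.5%, 15.7%, 14.4% and 13.6%. Foxf1 (chromosome 8, 109 CpGs) averaged 1.45%, then 1.43%, 1.53%, 1.84%, 2.37% and 2.04%. P3h3 (chromosome 6, 114 CpGs) averaged 15.0%, then 15.1%, 14.8%, 15.6%, 14.6% and 14.6%, and its tile shared with Gpr162 rose from 56.1% to 66.2% at day 3 (adjusted exact p = 3.97e-02). That difference lay close to the threshold of 10 points, and this tile was not called on both strands either. Over the 9 CpGs of the tile measured in all 6 libraries the levels were 60.6% and 62.3%.

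Of the 5 title genes 2 were higher and 0 lower at day 3, the same adjusted over the list alone, which is not independent evidence. None was called at day 14 or 28 against the uninjured library. Between the treadmill libraries of days 28 and 14, 1 was higher adjusted over the list alone and 0 over all tiles tested. The median of the list stood at percentile 90.3 at day 3, 97.1 and 98.1 at day 14 (cage, treadmill) and 40.7 and 44.9 at day 28. By the deposited criteria, an unadjusted p of at most 0.05 and a difference of at least 0.1, 10 CpGs of Peg12 were higher and 0 lower at day 28 with treadmill running. For Igfbp6 these counts were 5 and 0 at day 3 and 4 and 0 at day 14 with treadmill running, for P3h3 5 and 0 at day 28 with cage activity, and for Peg12 3 and 0 at day 3 and 4 and 0 at day 14 with cage activity. In the remaining pairs of these 5 genes with an injured library at most 2 CpGs met the criteria in either direction. At 1 CpG of Mmp25 chosen after its values were seen (chromosome 17, 23644123) the uninjured level was 6 of 17 reads, 35.3% (Wilson 95% interval 17.3% to 58.7%), and the injured levels were 57.1% to 76.2%. Among the CpGs of the 5 genes only 1, in Igfbp6 at day 3, was called.

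**Figure D5:**
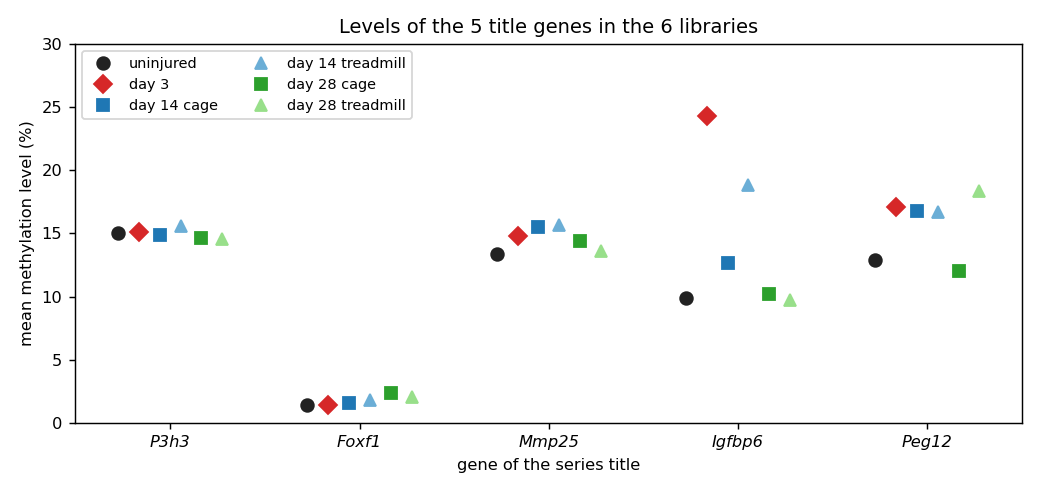
Mean methylation level (percent) of each of the 5 genes of the series title in each of the 6 libraries, over CpGs with at least 10 reads in all libraries. Igfbp6 is at 24.3% in the day 3 library and 9.89% in the uninjured library, and P3h3 lies between 14.6% and 15.6% in all.

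Treadmill running was compared with cage activity within each day, and thus among libraries whose names share a prefix. At day 14, Bmp1, which encodes a procollagen C-proteinase, was higher with treadmill running (64.5% against 26.7%, over 3 CpGs), as were Gcc1 (32.7 points), the endocytosis gene Ehd1 (30.7 points, adjusted exact p = 1.03e-08) and the fibrinogen gene Fga (30.1 points). Klhl9 was higher by 33.2 points, but with a minimum of 20 reads its difference was -1.74 points. The potassium channel gene Kcna3 (-36.9 points), Retnlb (-35.4), Fermt1 (-32.4), Tbc1d30 (-31.6) and Hoxc6 (-28.7, in a tile at 103010000) were lower. At day 28, the cytokine gene Il10 (86.9% against 51.1%), the tile of Hspb9 and Rab5c (36.1 points), Bcl2a1a (34.7), Atp6v0a1 (34.3) and Abcc9 (33.8) were higher with treadmill running. Dcpp1 (-44.7 points), the glutathione reductase gene Gsr (-41.5), Ggnbp1 (-36.8), the tile of Kctd11 and Tmem95 (-35.7) and Tceal9 (-30.7) were lower. None of these 20 named tiles could be measured on both strands.

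At day 14, 504 tiles were higher and 492 lower with treadmill running of 120744 (51 and 39 genes, 45 and 26 CpGs, or 37 and 39 with the strands of a CpG summed), and at day 28, 823 and 608 of 130276 (85 and 62 genes, 24 and 10 CpGs). Strands tested apart gave 497 and 466 tiles at day 14, beside 712 and 701 between the strands of the 2 libraries, and 694 and 776 at day 28, beside 727 and 939. The sign was shared by the other strand in 54.4% and 50.3%. In the direction of the call, tiles called on 1 strand averaged 19.5 and 20.3 points there. On the other strand they averaged 1.19 and 0.450 points. Of the tiles called on both days, 28 differed in 1 direction and 26 in opposite directions (51.9%, exact binomial p = 0.892), and no CpG was called on both days. Spearman's rho of the differences across tiles, which are not independent, was 0.00881. No gene-end tile with a gene symbol was called in 1 direction on both days. With a threshold of 20 points 38.5% were in 1 direction (exact binomial p = 0.581).

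List members named in this paragraph outside the naming rule were chosen after their values were seen. With treadmill running at day 14, limb and body-plan transcription factors had 2 higher and 4 lower of 72, the same adjusted over the list alone. The falls were at Hoxc6, Hoxc8 (-28.4 points), Tbx2 (-17.7) and Hoxb5, and the rises at Osr1 (12.5) and Emx2. TGF-beta and BMP signalling genes had 1 higher (Bmp1) and 1 lower (Bmp4, -20.2 points), and 2 and 1 adjusted over the list alone. With the same counts adjusted over the list alone, cartilage and bone genes had 1 higher (Chad, 16.6 points) and 1 lower (Comp), and 1 gene was lower in the IGF axis (Igfbp5, -16.9 points), among imprinted genes (Mcts2, -14.9 points) and among endothelial markers (Esam). The medians of the inflammation list (percentile 2.29) and the endothelial markers (2.02) were low. At day 28, limb and body-plan transcription factors had 3 higher (Hoxc9, 22.0 points, Hoxc8, 21.1, and Tbx18, 16.3) and 0 lower of 72, and 7 and 2 adjusted over the list alone. Imprinted genes had 2 higher, Peg3 and Usp29 in 1 tile, and Plod3 (30.6 points), Igfbp3 (19.2) and Il10 were the genes called, all higher, in the collagen-modifying, IGF and inflammation lists, with the same counts adjusted over the list alone. Skeletal muscle markers had 0 higher and 1 lower (Mylpf, -11.9 points), and 2 and 1 adjusted over the list alone, and keratinocyte markers had 1 higher (Cldn4, 13 points), and 2 adjusted over the list alone. In lists with 0 genes called at day 28, 1 cartilage and bone gene and 1 immune marker were higher, and 1 protease gene and 1 fat marker lower, adjusted over the list alone.

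Day 28 libraries were compared with day 14 libraries in each activity group. Pdgfra, the receptor gene for platelet-derived growth factor, was higher at day 28 by 19.7 points with cage activity and 18.3 points with treadmill running. Hoxc6 (15.3 and 11.6 points; chromosome 15, 103011000 to 103011999), the growth factor gene Fgf8 (16.1 and 10.8), Sh3tc2 (25.1 and 14.0) and Nudt4 (13 and 11.9) were also higher in both groups. The germ cell helicase gene Ddx4 (-20.3 and -27.1 points), Ms4a13 (-31.2 and -24.9), the antiproliferative gene Tob1 (-17.7 and -23.8) and the homeobox gene Gbx2 (-14.8 and -11.0) were lower in both. With cage activity 5 of these tiles could be measured on both strands, all with the same sign, and Hoxc6, Ddx4 and Gbx2 were called on both. With treadmill running 5 could be measured, of which Fgf8 had opposite signs (-8.10 and 4.54 points), and 0 were called on both. Limb and body-plan transcription factors had 7 higher and 0 lower with cage activity, the same adjusted over the list alone, where random lists gave a mean of 0.858 higher. With treadmill running they had 5 and 2, and 7 and 2 adjusted over the list alone, where random lists gave 0.723 higher.

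With cage activity 978 tiles were higher and 734 lower at day 28 of 106070 (113 and 69 genes, 210 and 152 CpGs). With treadmill running 994 were higher and 640 lower of 115837 (99 and 64 genes, 65 and 59 CpGs). Strands tested apart gave 784 and 722 tiles with cage activity, beside 908 and 479 between the strands of the 2 libraries, and 660 and 644 with treadmill running, beside 764 and 572. The sign was shared in 53.5% and 59.0%. The comparisons have no library in common. Of the tiles called in both, 78 differed in 1 direction (48 higher and 30 lower) and 36 in opposite directions (68.4%, exact binomial p = 1.04e-04), and of the CpGs 15 and 1. The day 28 libraries carry another name prefix than the day 14 libraries, so if the prefixes mark batches, day and batch cannot be told apart.

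The list members named next were chosen after their values were seen. With cage activity at day 28, 1 gene was higher in each of the cartilage and bone (Sox5, 25.3 points), TGF-beta and BMP (Tgfbr1, 10.3), protease (Mmp16, 16.3), imprinted (Plagl1), immune (Arhgap9, 40.7) and fat (Pck1, 10.3) lists. The tendon lineage and matrix gene Gdf5 was lower (-10.4 points). Adjusted over the list alone these counts were the same except for 1 further imprinted gene, lower, and 2 keratinocyte markers were lower. With treadmill running, imprinted genes had 3 higher and 0 lower, and 3 and 1 adjusted over the list alone. Bmp1 was lower (-43.3 points), Tnf was higher in the inflammation list (25.7 points) and the epidermal factor gene Grhl3 among keratinocyte markers (25.7 points). Adjusted over the list alone, 1 keratinocyte marker was lower besides, and 1 gene each of the collagen-modifying and IGF lists was higher. The median of the fat markers with treadmill running stood at percentile 1.66.

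The authors' deposited table of day 3 against uninjured placed 44318 CpGs in its classes of higher and 22609 in its classes of lower methylation in the injured library, 2.93% of the CpGs listed. The authors' deposited table for day 14 had 21721 and 21168 with cage activity, and 24307 and 23499 with treadmill running. The authors' deposited table for day 28 had 30717 and 20522, and 29086 and 19458. With each library in turn taken as the reference of those criteria over 1853317 CpGs, the number of CpGs that differed from it in all other libraries was 817 for the uninjured, 3700 for the day 3, 595 and 584 for the day 14 and 2610 and 1469 for the day 28 libraries. Simulated unchanged libraries gave a mean of 177 for the uninjured library, from 161 to 202. These simulations hold counting error only, leave out the spread between separate libraries and cover no other reference.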

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

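The gene-end tiles in this part were singled out after their values were seen, because treadmill running and cage activity differed in opposite directions on days 14 and 28, and the difference between the days was not tested. Each direction rests on 1 library per arm, and over all tiles 28 were called in 1 direction and 26 in opposite directions. The CpGs of a tile were selected for each day apart, so the values of the days can rest on different CpGs. At Crygn, a crystallin gene, the treadmill library was lower at day 14 (51.2% against 70.7%) and higher at day 28 (72.3% against 54.5%), so that the difference at day 28 minus that at day 14 was 37.2 points. At the predicted gene Gm39737 this value was 23.2 points. At Enpp6, a choline phosphodiesterase gene, the treadmill library was higher at day 14 (31.7% against 1.54%, 5 CpGs). It was lower at day 28 (6.15% against 22.9%, 10 CpGs), a change of -46.9 points. At the kinase gene Map4k5 it went from 58.5% against 34.0% to 38.2% against 60.3%, a change of -46.6 points. At the predicted gene Gm38636 the change was -25.7 points.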

How the results depend on the processing

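The counts with reads of both strands summed, with tiles called on each strand alone and without the day 3 library were chosen after seeing the data, and the other alternatives beforehand. Where no cause is given for a change, the cause was not tested.

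Counts of CpGs and tiles called per comparison stayed within 1.5 times their value, where each applied, with a minimum of 5 reads, with CpG thresholds of 10 and 30 points, with tiles of at least 5 CpGs, with read-weighted means and without X and Y. With the authors' deposited p, unadjusted, 47971 CpGs passed at day 3, 26962 and 31417 at day 14 (cage, treadmill) and 29750 and 28050 at day 28, all against the uninjured library, since no adjustment for the number of tests was made. This alternative was not run for the 4 comparisons without the uninjured library, which have no deposited p. With the deeper library thinned at each CpG, which leaves fewer reads, the CpGs called against the uninjured library were 612 at day 3, 40 and 84 at day 14 and 58 and 67 at day 28. For treadmill against cage they were 29 at day 14 and 2 at day 28, and for day 28 against day 14 they were 87 (cage) and 42 (treadmill). With the strands summed, which gives more reads per test, 2674 CpGs were called at day 3 and 56 for treadmill against cage at day 28. The higher and lower CpGs were then 126 and 163 for day 14 treadmill and 130 and 112 for day 28 treadmill against uninjured, and 37 and 39 for treadmill against cage at day 14, where they had been 114 and 104, 128 and 63, and 45 and 26. With a cap on coverage, 130 and 87 CpGs were called at day 28 against uninjured (cage, treadmill), and 223 and 77 for day 28 against day 14.

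With a minimum of 20 reads, which leaves fewer tiles, 5027 tiles were called at day 3, 975 and 923 at day 28 against uninjured (cage, treadmill), and 907 and 999 for day 28 against day 14. With a threshold of 20 points, which can only remove calls, the tiles were 4624 at day 3, 554 and 936 at day 14, 802 and 739 at day 28, 373 and 653 for treadmill against cage (days 14 and 28), and 671 and 700 for day 28 against day 14 (cage, treadmill). With sign flips over CpGs, which test only tiles of at least 6 CpGs and allow few of these a small p, the tiles in the same order were 827, 47, 90, 134, 125, 32, 112, 110 and 95. Called on each strand alone in 1 direction, which needs a call from fewer reads on both, they were 715, 48, 95, 52, 52, 23, 32, 33 and 39. Only tiles measured on both strands could be called so, 37997 at day 3 and 33751 to 39507 in the other comparisons. For day 14 treadmill against uninjured 470 tiles were higher and 466 lower with 20 points, 77 and 13 with sign flips and 66 and 29 on each strand.

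Mean methylation moved with the minimum of reads, because CpGs of low level are read more deeply. In the order uninjured, day 3, day 14 cage and treadmill, day 28 cage and treadmill it was 36.0%, 37.5%, 36.1%, 36.0%, 36.6% and 36.6% with 5 reads, and 14.1%, 15.0%, 14.3%, 14.3%, 14.6% and 14.5% with 20 reads, so that the day 3 library was highest in each. The uninjured library had rank 5 by CpGs at which it stood apart with a minimum of 5 reads and rank 3 without the day 3 library. The CpGs at which the day 3 and the uninjured library stood apart were 30576 and 16258 with 5 reads, 2366 and 438 with 20 reads, and 35180 and 24990 with all libraries thinned to 10 reads. Tiles called in 1 direction in 2 or more comparisons with the uninjured library were 886 with 20 reads, 619 with a threshold of 20 points and 990 without the day 3 library. Of the tiles called for treadmill against cage on both days, 38.5% were in 1 direction with a threshold of 20 points. The day 28 against day 14 share stayed on its side of an even split, at 67.0% to 90.9%, with exact binomial p from 1.25e-05 to 4.21e-04. With a minimum of 5 reads 16 list medians lay outside the central 95% of random lists, among them 6 of the 10 that did so with 10 reads. With 20 reads 4 of these 10 did so.

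Named tiles were counted once for each comparison in which they were named. Of 191 so counted, 140 were called again with a minimum of 5 reads, 47 kept their direction alone and 4 changed it. Among these 4 were Loxl4 with R3hcc1l at day 3 (-0.500 points) and H19 at day 28 with treadmill running (-8.61 points). The others were Gdf5 and Meg3 at day 14 with cage activity (-1.03 and -3.99 points). With 20 reads 59 were called, 26 kept their direction alone and Klhl9 for treadmill against cage at day 14 changed it (-1.74 points). The rest had too few CpGs of 20 reads to be tested. With the coverage cap all 191 were called, with read-weighted means 188 and with a threshold of 20 points 135. With at least 5 CpGs 107 were called, which were all that could be tested. Sign flips called 21 of the tiles tested, 70 keeping their direction alone. No paired analysis was possible because each group had 1 library. A median of 15 to 18 reads per CpG limits single CpGs. In data simulated for day 3, 0.274% of CpGs changed by 30 points were called. With only 200 tiles changed there the adjustment was stricter, so this share does not measure what depth alone allows.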

Other observations

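The tests of bisulfite conversion and of strand agreement at day 3 and the rank of the uninjured library were chosen after the result was seen, as were the counts without the day 3 library. The percentile of the immune markers at gene ends and the strand agreement per comparison were known when the remaining tests were written.

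The day 3 library differed at Hox genes beyond those named by rule, and the genes in this paragraph were chosen after their values were seen. Along the HoxC cluster on chromosome 15, gene-end tiles were lower in the day 3 library at Hoxc12 (22.5% against 41.7%, 20 CpGs), Hoxc10 (35.5% against 56.9%), Hoxc8 (26.4% against 42.1%, 38 CpGs) and Hoxc4 (23.5% against 39.0%). Hoxd12 (25.6% against 43.1%, 59 CpGs), Hoxa7 (12.2% against 34.9%) and the limb gene Irx3 (18.4% against 35.1%, 35 CpGs) were lower as well. Hoxb3 went the other way, with 25.5% against 9.20% over 32 CpGs of 1 tile and 31.7% against 9.38% in another, and Hoxb7 rose from 13.9% to 27.3%. Tiles inside genes, which the counts at gene ends leave out, gave 5 higher and 14 lower limb and body-plan transcription factors of 43 measured at day 3, where random lists had a mean of 2.29 lower. The median of -0.778 points lay below those of all 10000 random lists, beside 0.583 points over the random lists. Clustered Hox genes are not separate members as the genes of random lists are, so this standing may be overstated.

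Further tiles lower in the day 3 library, also chosen after their values were seen and not as a tested group, were those of the myeloperoxidase gene Mpo (35.5% against 73.0%, SD of the difference 12.8 points), Il21r (22.7% against 60.0%), the lymphocyte receptor gene S1pr4 (31.7% against 67.2% over 12 CpGs, adjusted exact p = 1.73e-17) and Batf, a transcription factor gene of T cells (30.7% against 72.5%). The fixed immune markers had 2 higher and 2 lower genes of 17 at gene ends, and 2 and 3 of 23 inside genes. Nfe2, of the erythroid lineage, had 1 tile lower (34.7% against 75.1%) and 1 higher (50.1% against 26.8%). The imprinted tiles of Peg13 and of Peg3 with Usp29 did not show the same order of libraries. Peg13 had 23.2% in the uninjured library, 27.7% at day 3, 29.8% and 47.2% at day 14 (cage, treadmill) and 43.2% and 31.0% at day 28. The tile of Peg3 and Usp29 had 38.6%, 34.9%, 29.8%, 31.2%, 22.9% and 52.4% in that order.

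The day 3 library stood apart from all others at 12174 CpGs, more than any other library, and at 35180 against 24371 to 30173 with all libraries thinned to 10 reads. Incomplete bisulfite conversion would raise CpGs that are nearly unmethylated elsewhere by about the rise of its mean level, 1.29 points. At the 502098 CpGs under 2% in the remaining 4 libraries, however, the day 3 level was 0.938% and the uninjured level 0.881%, a difference of 0.0573 points (0.0115 to 0.120 over 20 chromosomes), which argues against it. Amplified copies of few molecules would not be shared by strands. Of the calls on 1 strand, however, 85.2% had the same sign on the other, where a tile called on both enters once for each. This argues against that cause, while few fragments before conversion and differences between the mice stay open. Leukocytes in the injured tendon may contribute. The median of the immune markers at gene ends was -0.734 points, at percentile 1.21 of the random lists, which goes with this cause. That percentile was known before the test inside genes was written. Of the markers called at gene ends, Itgam and Itgal fell while Fcer1g (12.7 points) and the tile of Cd37 and Slc6a16 (24.1 points) rose. Inside the immune marker genes (1 of 35, Runx3, is also in the cartilage and bone list) the median stood at percentile 10.7. This lies between the values set for and against leukocytes as the cause, which therefore stay open. A response of tendon cells to injury stays open as untested.

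Tiles that differed between day 28 and day 14 in both activity groups did so more often in 1 direction (68.4%), at genes such as Pdgfra and Hoxc6. If the name prefixes mark batches and these were the cause, the uninjured library, of the prefix of day 14, should lie nearer to day 14, which it did in 53.3% of 75 tiles. This lies below the 75% set for a batch effect and above the 50% set against it, and day and prefix cannot be told apart by design. CpGs averaging under 2% in the other 5 libraries had 1.20% and 1.02% in the day 28 libraries (cage, treadmill). In the libraries of the other prefix such CpGs had 0.858% to 0.928%. At the same CpGs, under 2% in the remaining 4 libraries, day 3 minus day 28 was -0.293 points (cage) and -0.112 points (treadmill). The cause of this difference was not tested. Amplified copies of few molecules may account for part of the tiles. Of 68 calls on 1 strand shared by both activity groups, 73.5% (Wilson 95% interval 62.0% to 82.6%) had the same sign on the other strand. This lies between the bounds set beforehand, but a tile called on both strands enters once for each. Over all calls on 1 strand, shared or not, the share was 53.5% and 59.0% (cage, treadmill). For treadmill against cage it was 54.4% and 50.3%, and for day 28 against uninjured 57.4% and 59.6%. The bounds were set for shared calls when these shares were already known, so these shares do not test that cause. An effect of time after injury stays open as untested.

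Tiles called in 1 direction in 2 or more comparisons with the uninjured library, such as those at Nap1l5 and H19, may reflect injury or the 1 uninjured library itself. An effect common to all injured libraries, at more CpGs than differ between single libraries, would make the uninjured library stand apart most often. It had rank 4 of 6, behind the day 3 and the day 28 libraries. An effect of injury limited to some days would raise the counts of those libraries instead. The rank therefore cannot decide whether injury had an effect. Amplified copies of few molecules in the uninjured library would leave the strands unrelated. Of 1635 calls on 1 strand, 75.9% (Wilson 95% interval 73.8% to 77.9%) had the same sign on the other strand. A tile called on both strands enters once for each, which can raise the share, and the interval treats the calls as independent. Without the day 3 library the share was 66.4% of 934 calls (63.3% to 69.3%), nearer to the 60% set for that cause. With 1 uninjured library, its own deviation and an effect of injury cannot be told apart.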
